A study of Emberiza melanocephala with 4 samples.

How the data were processed

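RNA from hypothalamus and liver of wild-caught black-headed buntings was sequenced by pyrosequencing, per the labels' protocols. Total RNA had been extracted with a phenol-based reagent from tissue ground in liquid nitrogen. The authors' files hold 1 transcript assembly for each of the 4 libraries. Per the file headers, each was made with StringTie 1.3.3b from a trimmed alignment, guided by the Ensembl 89 annotation of the collared flycatcher (Ficedula albicollis, build FicAlb_1.4), another songbird. The aligner and the trimming tool are not given in the sources used here. The assembly was not limited to reference transcripts, per the file headers, so reference transcripts of the flycatcher and newly assembled ones stand side by side. All coordinates are those of the files, on the flycatcher build, and reads of a bunting aligned to another species can be lost where the sequences differ.

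For each transcript the deposited files give mean coverage per base, FPKM and TPM, inside a text field. FPKM was used throughout. Within a file the ratio of FPKM to coverage was 1 constant, at 63.3, 75.4, 48.1 and 56.2 for SD hypothalamus, LD hypothalamus, SD liver and LD liver. Under the definition of FPKM as coverage relative to all aligned bases, these constants give 15.8, 13.3, 20.8 and 17.8 aligned megabases. Read counts were not analysed here, so no counting interval is given. The deposited TPM values sum to 786913, 779219, 796211 and 789000, so that 21.3%, 22.1%, 20.4% and 21.1% of the TPM scale belongs to no listed transcript. The reason is not known, and low coverage is not shown to be the only reason that a locus is unlisted. The lowest coverage of an assembled transcript was 2.51, 2.50, 2.50 and 2.50, while reference transcripts were listed at any coverage, with medians of 0.38, 0.35, 0.33 and 0.48. An unlisted locus is therefore not a locus at 0, and no ratio was formed against one, except in the alternative that counts unlisted loci at 0. At the listing coverage of 2.5, an assembled transcript needs an FPKM of 158, 188, 120 and 141 in these libraries. Of the reference transcripts, 33 of 56, 93 of 183, 49 of 88 and 121 of 251 had a single exon. Whether such genes were more readily listed was not analysed.

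Groups were taken from the titles. The recorded seasonal state of 2 libraries contradicts the title (LD hypothalamus is recorded as short day and SD liver as long day). The command lines in the file headers name season and tissue as the titles do. They also carry run numbers 3, 1, 4 and 2 for SD hypothalamus, LD hypothalamus, SD liver and LD liver, which do not number replicates of a group.

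Transcripts of the 4 files were joined into loci when their exons overlapped by at least 1 base on the same strand or when they carried the same reference gene. Transcripts without a strand joined the stranded locus they overlapped most. This gave 750 loci, of which 278 had a gene symbol in the files, 103 a reference identifier only and 369 no reference gene. At 3 loci, TSC22D1, ACTB and DDX5, more than 1 reference gene was joined, and values of these loci are uncertain. No reference genome was used, so unnamed loci are given by position, and whether they are exonic or lie in a repeat was not analysed here. Because the library protocol is not stated to keep the strand, loci on opposite strands of the same interval cannot be separated with confidence. Members of near-identical families, such as actins, calmodulins and 14-3-3 proteins, may share reads and are uncertain in the same way.

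FPKM was summed per locus, and the log2 ratio of FPKM plus a pseudocount of 1 was formed for loci listed in both libraries of a comparison, which understates the change of low genes. A locus was called higher or lower at a ratio of 2 or more. There was no test, since each group has 1 library. The 4 comparisons, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each comparison, the 10 highest and 10 lowest log2 ratios, the 5 highest FPKM of each library, the 5 highest FPKM listed in only one library, and every listed member of the 25 fixed lists (522 genes). Unnamed loci were limited to the first 5 of each kind, and some genes that the rule takes are not reported here. Additional genes listed in only one library were picked among those with a symbol after their values were seen. A list median was to be set against 10000 random lists of the same size, for lists with at least 3 members in both libraries, which no list had.

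The same locus can be measured on a short assembled transcript in 1 library and on a longer reference transcript in another, and FPKM then differs with the length. For this reason a scale without division by transcript length, called length-free here, was added after seeing the data. It is aligned bases (coverage times transcript length) per aligned megabase, again with a pseudocount of 1. At equal coverage a longer transcript holds more aligned bases. The scale thus still depends on the transcripts compared and does not correct for their length. The share of loci with the same reference transcripts in both libraries was 21 of 32 for hypothalamus by season, 33 of 53 for liver by season, 26 of 67 for the short-day tissue pair and 92 of 142 for the long-day tissue pair.

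Alternatives were pseudocounts of 0.1 and 10, the upper part of loci by mean FPKM, scaling to an equal total, median-ratio scaling, the highest transcript of a locus, a ratio of 4, a reciprocal overlap of 50% and unlisted loci at 0. The length-free scale and a restriction to loci with the same reference transcripts were added after seeing the data. The code was tested on simulated data, in which 100% of planted 4-fold changes were recovered for hypothalamus by season, 99% for liver by season, 100% for the short-day tissue pair and 97% for the long-day tissue pair, with 0 false calls over 750 simulated loci each. The simulated noise was small next to the median absolute log2 ratios between these libraries (0.62 to 1.02 outside the 10 highest loci). The simulation thus checks the code and does not give the rate of false calls in these libraries. Computations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.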

Results

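RNA of the black-headed bunting (Emberiza melanocephala), a migratory songbird, was profiled in hypothalamus, the brain region that controls seasonal reproduction and feeding, and in liver, the main organ of fat and carbohydrate metabolism. Wild-caught birds were sampled in a short-day (SD) and a long-day (LD) state, and total RNA was sequenced by pyrosequencing, a method that yields few but long reads. The 4 libraries are 1 each of SD hypothalamus, LD hypothalamus, SD liver and LD liver. With 1 library per group no difference has a replicate check, and no p-value or error is given. The titles name both tissue and season, but the seasonal state recorded for 2 libraries, titled LD hypothalamus and SD liver, contradicts their titles. Groups follow the titles, and marker genes described in the next paragraphs go against the tissue label of 2 libraries, so each library is called by its label throughout. The comparisons are those of the labels, and they do not settle whether a difference belongs to season or to tissue.

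The depth was low, and a few loci took up most of the listed sequence. From the ratio of FPKM to coverage, the aligned sequence came to 15.8, 13.3, 20.8 and 17.8 megabases in the libraries labelled SD hypothalamus, LD hypothalamus, SD liver and LD liver. The files list 111, 293, 184 and 488 transcripts in this order, at 106, 280, 175 and 473 loci. The 10 highest loci together held 97.0%, 94.1%, 96.3% and 90.1% of the summed FPKM of listed loci. Of the aligned megabases, which include unlisted sequence, they held 7.10, 4.85, 9.80 and 5.86. The highest of all, an assembled locus with no reference gene on the minus strand of scaffold JH603816.1 (22792 to 24744), had 253430, 198971, 286579 and 174825 FPKM. Next came 2 short annotated features of scaffold AGTO01023469.1, ENSFALG00000015904 (1392 to 1457; 136122, 106576, 144047 and 104682 FPKM) and ENSFALG00000016074 (1959 to 2009; 127366, 98483, 133670 and 95457 FPKM). The plus strand of the same JH603816.1 interval and a locus on JH604008.1 (14138 to 14467) completed the 5 highest of every library, and neither has a gene symbol. Of the aligned sequence, 53.1%, 59.5%, 50.3% and 60.5% lay in no listed locus, and listed loci outside the 10 highest held 0.298, 0.529, 0.522 and 1.16 megabases.

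Across the 4 libraries, 750 loci were listed, 278 of them with a gene symbol. Of these loci, 537 were listed in 1 library, 165 in 2, 25 in 3 and 23 in all 4. The 6 named genes listed in all 4 libraries were SLC25A6, which encodes an ADP/ATP carrier of mitochondria, the translation factor EIF4A2, the cytoskeletal actin ACTB, the glycolytic enzyme GAPDH, the nuclear receptor co-repressor NRIP1 and LRRC8D, a subunit of volume-regulated anion channels. The libraries labelled SD hypothalamus and SD liver shared 67 loci, 31.3% of those listed in either, and those labelled LD hypothalamus and LD liver shared 142, or 23.2%. The libraries with the same tissue label shared less, 32 loci (9.04%) for hypothalamus and 53 loci (8.91%) for liver. These shares depend on list length. Of the smaller list, the SD pair shared 63.2%, the LD pair 50.7%, SD hypothalamus and LD liver 46.2%, and the pairs of the same tissue label 30.2% and 30.3%. Only the SD pair shared more loci than independent lists among the 750 would (67 against 24.7). The LD pair shared fewer (142 against 177). The 750 are only the loci listed in some library, which sets this expectation too high, the more so for long lists. A count below it, as for the LD pair, thus does not show low sharing. A locus that is missing from a file is described as not listed and not as absent. Assembled transcripts below a coverage of about 2.5 do not appear, and other reasons are not excluded.

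**Figure D1:**
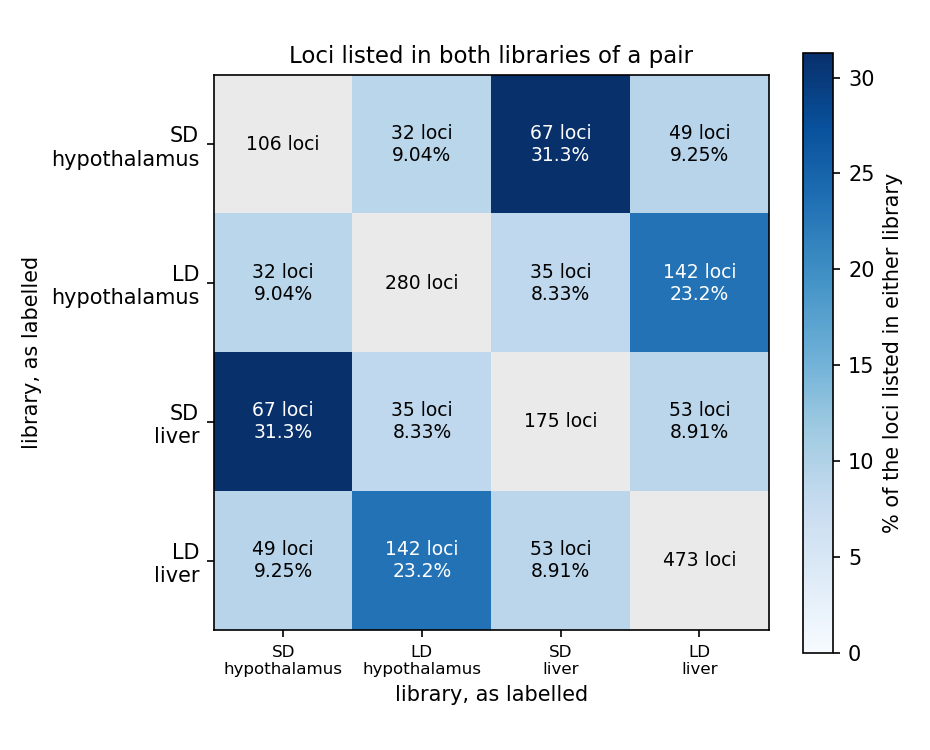
Number of loci listed in both libraries of each pair, with the colour and the lower figure giving the percent of the loci listed in either library; the diagonal gives the loci of each library. The pairs with the same labelled season share 31.3% and 23.2%, and all other pairs share 8.33% to 9.25%.

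Apart from APOA1, listed members of the neuron, myelin, astrocyte and neurotransmitter lists appeared only in the libraries labelled LD. Of the neuron list, SNAP25, a membrane fusion protein of synaptic vesicles, had 290 FPKM in LD hypothalamus and 462 FPKM in LD liver, and GAP43, a protein of growing axons, had 38.8 and 26.1 FPKM. STMN2, a tubulin-binding protein of neurons, was listed only in the library labelled LD liver (46.9 FPKM), as was SLC32A1, the vesicular carrier of GABA and glycine (26.8 FPKM), the 1 listed gene of the neurotransmitter list. GPM6B, a membrane protein of glia and neurons from the myelin list, had 91.2 and 87.1 FPKM in the LD pair, and SPARC, a matrix glycoprotein on the astrocyte list, had 41.5 and 244 FPKM. None of these 6 genes was listed in the library labelled SD hypothalamus or in that labelled SD liver. APOA1, the main protein of high-density lipoprotein and the 1 listed member of the lipid transport list (also on the astrocyte list), had 327 FPKM in SD hypothalamus, 655 in SD liver and 20.9 in LD liver, and was not listed in LD hypothalamus.

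Genes of sugar metabolism and of the clock were sparsely listed. In the glycolysis list, GAPDH was listed in all 4 libraries and TPI1, triosephosphate isomerase, in 3 (24.1 FPKM in SD hypothalamus, 13.6 in SD liver and 22.6 in LD liver). In the circadian list, the transcriptional repressor NFIL3 had 82.7 FPKM in SD hypothalamus, 13.1 in SD liver and 3.93 in LD liver, and BHLHE40, another repressor of clock genes, was listed only in LD hypothalamus (35.0 FPKM). Of the mitochondrially encoded list, COX1, a subunit of cytochrome c oxidase, had 2.56 FPKM in LD hypothalamus and 1.02 in SD liver. These values rest on 53 and 33 aligned bases and are not secure. The ribosomal proteins RPLP0 (36.4 FPKM, SD liver) and RPS3 (27.8 FPKM, LD hypothalamus), the chaperone HSPA2 (21.8 FPKM) and the tight-junction protein CLDN5 of endothelium (13.9 FPKM), both in LD hypothalamus, were each listed once. SLC25A6 was the only listed member of the oxidative phosphorylation list.

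The other 13 of the 25 lists had no listed member in any library. They are the photoperiodic and reproductive axis, hypothalamic neuropeptides, lipogenesis, fatty acid oxidation, cholesterol and bile acid metabolism, hepatocyte secreted proteins, hepatocyte metabolic enzymes, acute phase genes, egg yolk precursors, oxidative stress defence, red blood cells, pituitary and muscle. At this depth their absence from the files does not show absence from the tissue. Lists were matched by gene symbol. Members of any list among the 103 loci with an identifier only, or the 369 with no reference gene, could therefore not be seen. No list had 3 members listed in both libraries of any comparison, so no list median was formed.

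**Figure D2:**
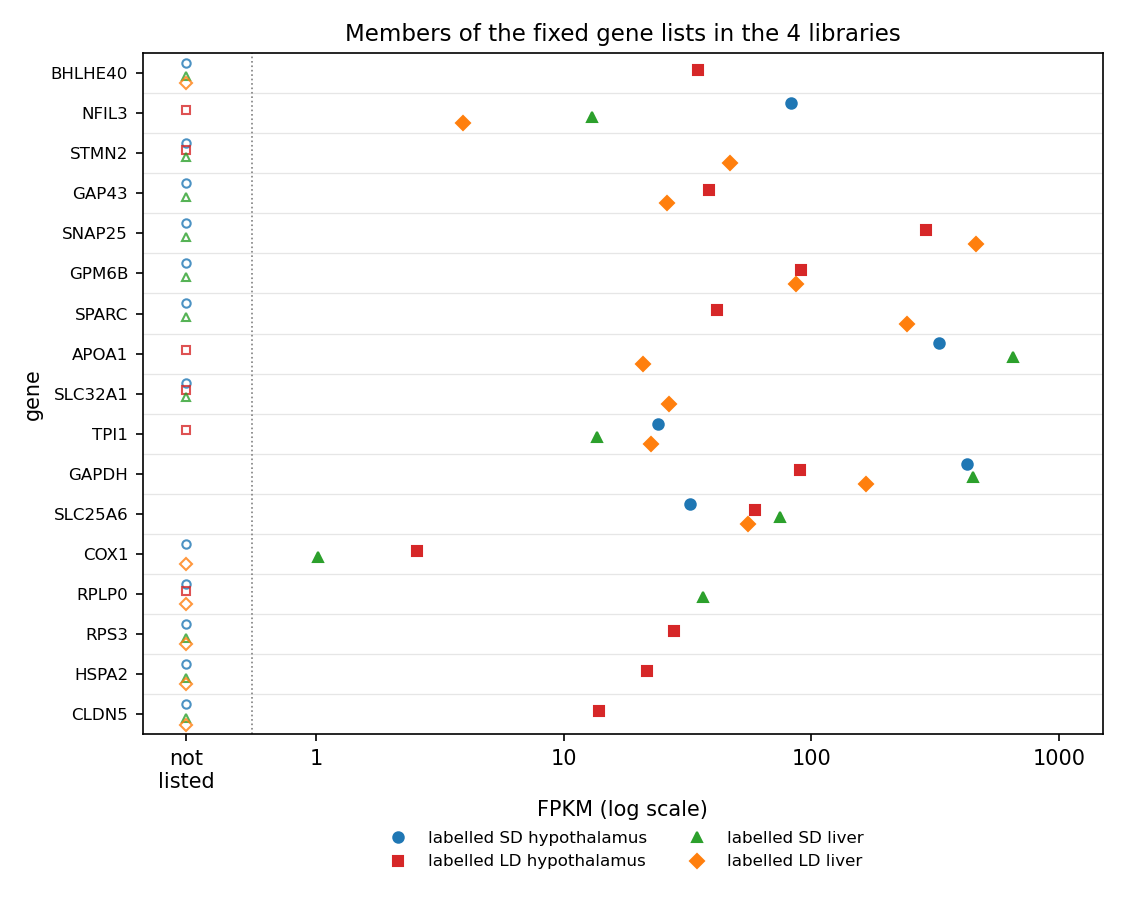
FPKM, on a log axis, of the members reported here of the gene lists fixed before the data were examined, with 1 marker per library and open markers at the left for genes not listed. SNAP25, GAP43, GPM6B and SPARC appear only in the libraries labelled LD, while APOA1 has 327 and 655 FPKM in those labelled SD.

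The first comparison sets the library labelled LD hypothalamus against that labelled SD hypothalamus. Of the 32 loci listed in both libraries labelled hypothalamus, 7 were at least 2-fold higher and 4 at least 2-fold lower in LD, around a median log2 ratio of -0.27. The highest log2 ratio was that of CALM3, which encodes the calcium sensor calmodulin (3.89; 9.88 FPKM in SD and 160 in LD; scaffold JH603202.1, 4501811 to 4511250). YWHAQ, a 14-3-3 signalling adaptor, followed at 3.42 (6.32 and 77.1 FPKM), the translation factor EIF4G2 at 2.87 (36.2 and 270 FPKM), the actin-depolymerising protein DSTN at 2.67 and the dynein light chain DYNLL2 at 2.66. NRIP1 stood at 1.06, and SLC25A6 (0.85) and EIF4A2 (0.54) stayed within 2-fold. A mitochondrial feature at 1120 to 2715 of the mitochondrial sequence, ENSFALG00000016233, was higher in LD at a log2 ratio of 1.34 (855 and 2169 FPKM).

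GAPDH had the lowest log2 ratio, -2.23 (426 FPKM in SD and 89.8 in LD; scaffold JH603259.1, 1244147 to 1252064). That value rests on an assembled transcript of 1153 bases in SD and a reference transcript of 6021 bases in LD. On aligned bases per megabase, a scale not divided by transcript length (called length-free here), the log2 ratio was 0.14. A longer transcript can gather more bases on this scale, so it does not correct for length. ACTB likewise moved from -0.38 to 0.54. Below GAPDH in size were unnamed loci on JH603866.1 (8855 to 9741, at -1.73) and JH603257.1 (3400656 to 3404379, at -1.72). On the length-free scale they were at -1.04 and -1.73. Of the 11 loci at least 2-fold apart, 9 remained so in the same direction on the length-free scale. On that scale the 7 with the same reference transcripts could change little except through the pseudocount. ENSFALG00000014531, among these 7, went from -1.11 to -0.96.

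Most named genes stood in only one of these libraries. The library labelled SD hypothalamus alone listed 23 genes with a symbol, led by APOA1 (327 FPKM), SAR1B, a GTPase of secretory vesicle budding (101 FPKM), NFIL3 (82.7 FPKM), PAICS, an enzyme of purine synthesis (78.9 FPKM), and ARF6, a GTPase of membrane traffic (74.1 FPKM). The library labelled LD hypothalamus alone listed 118, led by CKB, the brain-type creatine kinase (375 FPKM), SNAP25 (290 FPKM), the 14-3-3 adaptor YWHAH (226 FPKM), the proton pump subunit ATP6V1C1 (224 FPKM) and the ubiquitin-conjugating enzyme UBE2K (220 FPKM). PVALB, a calcium buffer of fast-spiking neurons and muscle (205 FPKM), and OLFM1, a secreted glycoprotein of neurons (201 FPKM), were in this set too. Apart from APOA1, NFIL3, CKB and SNAP25, these single-library genes were chosen after their values were seen.

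The second comparison sets the library labelled LD liver against that labelled SD liver. Of the 53 loci listed in both libraries labelled liver, 10 were at least 2-fold higher and 10 at least 2-fold lower in LD, around a median log2 ratio of -0.36. The lowest log2 ratio was that of APOA1, -4.91 (655 FPKM in SD and 20.9 in LD; scaffold JH603405.1, 184244 to 186123), and it was -4.11 on the length-free scale. The splicing factor SRSF6 was lower at -3.01 (30.7 and 2.92 FPKM), NFIL3 at -1.51 and MDH1, cytosolic malate dehydrogenase, at -1.25 (74.9 and 30.9 FPKM). The highest were ZBTB42, a zinc-finger protein (3.66; 2.36 and 41.5 FPKM), the sorting nexin SNX12 (2.83; 24.8 and 183 FPKM), the membrane ubiquitin ligase RNF139 (2.24), the zinc-finger and homeobox protein ZHX1 (2.03) and the glycosyltransferase B3GNT2 (1.75). OAZ1, which restrains polyamine synthesis, stood at 1.65 (79.9 and 253 FPKM) and EIF4A2 at 1.57 (144 and 430 FPKM).

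The RNA helicase DDX5 had a log2 ratio of 1.70, but it was represented in SD by a feature of 124 bases and in LD by transcripts of 3873 bases. Its locus also joins more than 1 reference gene, so the value is uncertain. On the length-free scale, where longer transcripts can gather more bases, it was 6.17. GAPDH was at -1.43 in FPKM and at 0.92 on the length-free scale, again with transcripts of different length. Dividing each library by its median ratio to remove that median shift changed the split of the loci at least 2-fold apart from 10 higher and 10 lower to 16 higher and 7 lower.

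Among named genes, 39 were listed in SD liver and not in LD liver, and 158 the other way round. The SD set included PAICS (143 FPKM), AHCY, which hydrolyses S-adenosylhomocysteine (65.1 FPKM), the nucleic-acid-binding protein CNBP (62.2 FPKM) and ADH5, the formaldehyde-oxidising alcohol dehydrogenase (37.3 FPKM). The LD set was led by SNAP25 (462 FPKM), CKB (366 FPKM), CPE, which trims peptide hormones and neuropeptides (348 FPKM), CALM3 (346 FPKM) and OLFM1 (277 FPKM). SNAP25, CKB and OLFM1 thus stood in both libraries labelled LD and in neither labelled SD. Except for SNAP25, these single-library genes were chosen after their values were seen.

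The remaining comparisons set liver against hypothalamus within each labelled season. In the short-day pair, 67 loci were listed in both libraries, of which 5 were at least 2-fold higher and 9 at least 2-fold lower in liver. SLC25A6 was higher in SD liver (log2 ratio 1.17; 32.5 and 74.6 FPKM), and NFIL3 (-2.57), NRIP1 (-2.04), ZBED4, a zinc-finger protein (-1.97), and RNF139 (-1.26) were lower. APOA1 stood at 1.001, a value that was 0.18 on the length-free scale. The translation factor EIF5 had the highest ratio, 1.68, from a transcript of 3405 bases in SD hypothalamus and 1 of 534 bases in SD liver, and its sign turned to -0.95 on the length-free scale. PAICS turned likewise, from 0.85 to -1.38. ACTB, lower in SD liver at -1.19, was at -0.29 on that scale.

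The lowest ratio of the short-day pair, -6.06 for ENSFALG00000011757 (JH603331.1, 169040 to 174986), set a transcript of 324 bases against 1 of 4475 bases and was -2.66 on the length-free scale. Of the 14 loci at least 2-fold apart, 8 remained so on that scale in the same direction. The 5 with the same reference transcripts could change little except through the pseudocount, which took NRIP1 from -2.04 to -2.52. Among loci listed in only one library of the pair, 18 named genes were in SD hypothalamus and 49 in SD liver, the latter including AHCY. ONECUT1, a transcription factor of liver and pancreas, had 10.9 FPKM in SD hypothalamus and 11.1 in SD liver and was in neither LD library. It was chosen after its values were seen.

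In the long-day pair, 142 loci were listed in both libraries, 20 at least 2-fold higher and 18 at least 2-fold lower in liver, with a median log2 ratio of 0.03. The highest named genes were the glycosyltransferase B3GALT2 (3.66; 0.86 and 22.5 FPKM), the serotonin receptor HTR1B (2.87; 13.5 and 105 FPKM), SPARC (2.53; 1.45 on the length-free scale), CPE (1.98; 0.45 on that scale), the sulfotransferase CHST1 (1.81) and the sphingosine-1-phosphate receptor S1PR1 (1.79; 31.3 and 111 FPKM). The lowest were PVALB (-3.61; -1.04 on the length-free scale), UBE2K (-2.83), NRIP1 (-2.73; 17.0 and 1.71 FPKM), HPS6, a factor of lysosome-related organelles (-2.62), the actin regulator PFN2 (-2.57), the ubiquitin ligase TRIM13 (-2.54) and DYNLL2 (-1.73). B3GALT2 rests on 14 aligned bases in LD hypothalamus, so the size of its ratio is not secure. Over the 4 comparisons, 22 of the 83 ratios of 2-fold or more rest on fewer than 150 aligned bases in a library, a limit chosen after seeing the data. They include ZBTB42, RNF139, NFIL3 and DDX5 between the liver labels, RNF139, ZBED4 and NRIP1 in the short-day pair, and HPS6, TRIM13, NRIP1 and PFN2 in the long-day pair. Of the 38 loci at least 2-fold apart, 33 remained so in the same direction on the length-free scale. On that scale the 28 with the same reference transcripts could change little except through the pseudocount.

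Genes found in 1 library of the long-day pair numbered 51 with a symbol in LD hypothalamus and 106 in LD liver. Those of LD hypothalamus were led by CNBP (220 FPKM) and the 14-3-3 adaptor YWHAB (79.2 FPKM), and those of LD liver included SNX12 (183 FPKM) and the vesicle GTPase RAB11B (126 FPKM), all chosen after their values were seen.

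Whether the difference between labelled seasons was alike under both tissue labels could be described at the 23 loci listed in all 4 libraries. The LD to SD log2 ratios of hypothalamus and liver had a Pearson r of 0.63 and a Spearman rho of 0.60 across these loci, which are not independent replicates. The ratios had the same sign at 18 loci, and none was at least 2-fold apart in opposite directions. The ratios differed by 2-fold or more at 4 loci, namely SLC25A6 (0.85 in hypothalamus and -0.42 in liver), EIF4A2 (0.54 and 1.57), ACTB (-0.38 and 0.84) and the mitochondrial feature ENSFALG00000016231 at 68 to 1050 (-0.39 and 1.63). For ACTB the length-free values were 0.54 and 1.03. An interaction could not be tested with 1 library in each combination.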

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

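At 5 of the 23 loci listed in all 4 libraries, the LD to SD ratio had opposite signs in the libraries labelled hypothalamus and liver. With 1 library per group, the differences between the tissues were not tested. The log2 ratio of liver minus that of hypothalamus was -1.27 for SLC25A6, the mitochondrial ADP/ATP carrier (0.85 in hypothalamus and -0.42 in liver). It was 1.22 for ACTB (-0.38 and 0.84), whose signs no longer differed on the length-free scale (0.54 and 1.03), a scale chosen after seeing the data. The mitochondrial feature ENSFALG00000016231 (68 to 1050) had a difference of 2.02 (-0.39 and 1.63), and a locus with no reference gene on JH603387.1 (81552 to 89354) had -0.90 (0.40 and -0.49). The plus-strand locus on JH603816.1 (22792 to 24740), one of the 10 highest, had 0.58 (-0.03 and 0.55).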

How the results depend on the processing

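The length-free scale and the restriction to loci with the same reference transcripts were chosen after seeing the data; the cause of a move was not tested unless stated. Season with tissue as a block, over all 4 libraries, was not run. Ratios with non-overlapping FPKM intervals were not run, since no intervals were used here, and no library could be left out of a comparison of 1 against 1. The 11, 20, 14 and 38 loci at least 2-fold apart (hypothalamus by season, liver by season, short-day tissues, long-day tissues) became 4, 9, 4 and 10 in the upper part by mean FPKM and 6, 8, 3 and 12 at a ratio of 4, where fewer loci can pass by construction. With unlisted loci counted at 0 they became 330, 559, 161 and 506. With the same reference transcripts only they became 7, 11, 5 and 28, the last within 1.5 times. A pseudocount of 10 left 9 for the short-day tissues. All other settings kept the 4 counts within 1.5 times. Median-ratio scaling and equal totals both gave 16 higher and 7 lower for liver by season, against 10 and 10. For hypothalamus by season the split was 1 higher and 3 lower in the upper part and 8 and 2 on the length-free scale, against 7 and 4. In the upper part it was 3 and 6 for liver by season, 3 and 1 for the short-day tissues, against 5 and 9, and 4 and 6 for the long-day tissues, against 20 and 18. With the same reference transcripts only it was 6 and 1 for hypothalamus by season, 7 and 4 for liver by season and 1 and 4 for the short-day tissues, and at a ratio of 4 it was 5 and 1 for hypothalamus by season, 0 and 3 for the short-day tissues and 5 and 7 for the long-day tissues. With unlisted loci at 0 it was 252 and 78, 427 and 132, 113 and 48, and 350 and 156. The 23 loci listed in all 4 libraries were 21 under a reciprocal overlap of 50% and 23 above the FPKM floor. That floor, 0.165, lies below every value of these loci (lowest 1.09, NRIP1 in SD liver), so it could remove none. The season correlation of 0.63 was 0.62 with median-ratio scaling, 0.67 with a pseudocount of 10, 0.82 in the upper part and 0.64 on the length-free scale. For the 65 ratios at least 2-fold apart that the rule for named genes takes, 569 values under alternatives were formed, of which 268 were the same, 295 moved and 6 changed sign. The rule leaves out 18 such loci of the long-day tissues, of which 1, ENSFALG00000007917, went from -1.34 to 0.87 on the length-free scale. Smaller ratios, such as those of PAICS in the short-day tissues and ACTB in hypothalamus, also changed sign. On the length-free scale GAPDH was 0.14 in hypothalamus and 0.92 in liver, EIF5 was -0.95 in the short-day tissues, and in the long-day tissues ENSFALG00000008805 was 0.998 and ENSFALG00000013131 was 0.35, each with transcripts of different length. ENSFALG00000016215 was -0.49 in the long-day tissues under reciprocal overlap. Depth limits all of this, with at most 1.16 megabases in listed loci outside the 10 highest.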

Other observations

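All tests in this part were chosen after the results were seen. Many genes with known roles in neurons were listed in the libraries labelled LD and in neither labelled SD. A set of 45 such genes, picked after their values were seen and only from listed genes, had 30 members in LD hypothalamus, 38 in LD liver, and 0 in SD hypothalamus and in SD liver. Of these genes 5 are also on the fixed lists, and the other 40 had 27 members in LD hypothalamus and 33 in LD liver. It holds the potassium channels KCNA1 (68.9 FPKM in LD hypothalamus and 39.8 in LD liver) and KCNA2 (78.5 and 32.0), the synapse-organising membrane proteins LRRTM1 (63.1 and 112), SLITRK1 (38.7 and 18.0) and LRRC4C (20.5 and 57.5), the axon growth inhibitor receptor component LINGO1 (44.5 and 82.6) and the serotonin receptor HTR1B. Found only in LD liver were the dopamine receptor DRD1 (10.4 FPKM), the neuronal transcription factor NEUROD6 (14.9), ZIC1 (38.1) and SOX2 (106), a factor of neural progenitors. The set was drawn from these libraries and is not independent evidence of their grouping.

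Of 9 genes typical of liver picked in the same way, 2 of them on the fixed lists, 3 were listed in SD hypothalamus, 0 in LD hypothalamus, 8 in SD liver and 1 in LD liver. The gap junction protein GJB1 (14.8 FPKM) was listed only in SD hypothalamus. Whether the 9 genes are specific to liver was not tested, and APOA1, among the 3 in SD hypothalamus, is also on the astrocyte list. PCBD1, a cofactor-recycling enzyme (30.7 FPKM), the electron carrier CYB5A (23.6 FPKM) and the transcription factor CEBPB (10.8 FPKM) were listed only in SD liver.

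By the share of loci listed in either library, the libraries group by labelled season and not by labelled tissue. Other measures are mixed. Of the smaller list, SD hypothalamus and LD liver shared 46.2%, close to the 50.7% of the LD pair. Outside the 10 highest loci, Pearson r across shared loci was highest for LD hypothalamus and SD liver (0.91, 25 loci). It was 0.89 for the SD pair (57 loci) and 0.84 for the LD pair (132 loci). The median absolute log2 ratio at the same loci went with the grouping by labelled season. It was smallest for the LD pair (0.62) and the SD pair (0.69), against 0.75 to 1.02 for all other pairs. A lower depth of the library labelled SD hypothalamus is argued against (counts by listing level, here and for the carry-over, leave out the 10 highest loci): of 114 LD hypothalamus loci with an FPKM at which SD hypothalamus would list an assembled transcript, it listed 8.77%, against 44.3% of 115 such loci in LD liver (at 2 and 4 times that level it listed 5 of 13 and 3 of 3). A candidate explanation is that the tissue labels of SD hypothalamus and LD liver were exchanged: of the 68 genes on 4 brain lists fixed before the data were examined, leaving out 3 also on liver lists, 6 were listed in LD liver, 4 in LD hypothalamus and 0 in either SD library, and APOA1 was listed in SD hypothalamus but not in LD hypothalamus. These counts were known when the explanation was put forward, so they are not an independent test of it. Support from the liver side is thin: APOA1 was listed in LD liver as well (20.9 FPKM), and of the 154 other genes on 6 liver lists 0 were listed by symbol in any library. Members among the loci without a symbol could not be seen. Carry-over of hypothalamus RNA into the LD liver library is argued against as the whole cause, since it leaves SD hypothalamus untouched. Of 35 SD liver loci above the listing levels of both hypothalamus libraries, SD hypothalamus listed 82.9% and LD hypothalamus 17.1%; with 1 library each, how far such shares vary between libraries is not known. For LD liver alone, partial carry-over cannot be told apart from an exchange, because few loci are abundant enough: of SD liver loci that LD hypothalamus does not list, LD liver listed 40% of 5 at 4 times its listing level, 11.1% of 18 at 2 times and 14.6% of 48 at 1 time. An effect of season on both tissues was not tested and stays open, and the recorded seasonal states, short day for both hypothalamus titles and long day for both liver titles, leave the season of LD hypothalamus and SD liver open as well. An exchange of the whole libraries would leave the season of SD hypothalamus and LD liver open too. Unlike an exchange of tissue labels alone, it would keep both tissues under both states. Under either exchange, both season comparisons set brain against liver, and each comparison of labelled tissues lies within a single tissue. The ratios of CALM3 and APOA1, the genes found in 1 library and the correlation of 0.63 between the tissues would then include a tissue difference.

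GAPDH was lower in both libraries labelled LD in FPKM, at log2 ratios of -2.23 and -1.43. Transcript models of different length may account for this: on aligned bases per megabase the ratios were 0.14 in hypothalamus and 0.92 in liver, so that it was not lower in either. That scale cannot settle the direction, since the transcripts in LD were longer and can gather more bases. No biological explanation was tested.

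The libraries labelled SD listed fewer loci than those labelled LD. A few loci taking a large part of the sequence could leave less for the rest, and this stays open. The aligned bases outside the 10 highest loci were 1.03 times as many in SD as in LD hypothalamus (8.69 and 8.42 megabases), and 10.98 megabases in SD liver against 11.9 in LD liver. More than 50% of the aligned bases of each library lie in no listed locus, and what they belong to is not known, so these values decide nothing. A difference of tissue or season was not tested and stays open.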
